A study of Homo sapiens with 4 samples.

How the data were processed

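RNA from human cells was measured on 4 Affymetrix exon arrays, with 2 arrays of fallopian tube stem cells (FTSC) and 2 of the same kind of cell after differentiation at an air-liquid interface (FTSC-ALI). Per the labels, the stem cells were grown on 3T3 feeder cells and differentiated with an air-liquid interface system. Per the labels' design text, stem cell RNA was isolated with the PicoPure kit and FTSC-ALI RNA with the RNeasy kit. Kit and group therefore cannot be told apart in any comparison given here. Whether RNA of the feeder cells reached any array was not tested, which also bears on every comparison. Groups and replicate numbers were taken from the sample titles.

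The deposited table holds 1 value per transcript cluster and array, called a feature here, for 22011 features. The authors deposited these as log-scale values, read here as log2 because they ran from 0.846 to 12.7, the range of such an array. The log base, the summarization and the normalization are not given in the sources used here. Per the submitters' processing notes, Affymetrix Expression Console and Partek were used with genome build hg18, with no version or role given. The values were analysed as deposited, without further scaling. Array medians were 4.75 and 4.70 in FTSC and 4.69 and 4.67 in FTSC-ALI. No detection calls were used here, so a low value was not judged against background, and the number of arrays limits the precision. If the base were not 2, the folds, the 2-fold counts and the comparison of shares on unlogged values would change. The limma and camera tests would not.

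Gene symbols came from the platform annotation table, updated through Entrez identifiers with an NCBI gene table of assembly GRCh38.p14, in which 14404 of the 14432 features with 1 symbol matched. Several symbols were given for 2408 features, and 5171 were not named here. No gene was named from a feature with several symbols. No coordinates are given, because the gene table and the submitters' notes use different builds. Where a gene had more than 1 feature, the brightest over the 4 arrays was used. Of the 197 such genes, 0 had features called in opposite directions by limma. Control features were not identified from the tables used here, so all 22011 features entered the fit. Fits restricted to features with 1 symbol, or with at least 1, were run as alternatives, the latter chosen after seeing the data.

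Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment over all features, called at an adjusted p under 0.05). The fit had 2 residual degrees of freedom, a prior of 3.30 degrees of freedom and a prior SD of 0.160. Differences are FTSC-ALI minus FTSC. The labels do not say whether replicates came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Equal replicate numbers were not used to pair arrays.

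The 32 gene lists, the rule for named genes, the main test and the alternatives to it, except where stated, were set before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists, and called at an adjusted p under 0.05. The same test with a correlation estimated per list called none of the 32. Members were also counted after adjustment over the list alone. Named genes were the 12 largest called increases and the 12 largest called decreases among features with 1 symbol, up to 4 leading and 2 opposing called members per list, and a fixed set of 19 genes. Of that set, KRT5 and SOX2 lay only on features shared with another gene, and TP63, MUC16 and GAPDH were not analysed here.

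The procedure was tested on simulated data in 5 simulations of 22011 features with 200 changed. The share of changed features called was 0% at a log2 change of 0.5, 1.49% at 1 and 76.4% at 2, and 5.86% of calls were false. In the same simulations, camera with the preset correlation called 25 of 25 lists shifted by 0.5 and 0 of 135 unshifted lists. With an estimated correlation it called 0 of the 25 shifted lists, so at a shift of 0.5 a missing call in that setting says little. Larger shifts were not simulated. Simulated features were drawn independently of each other. The 0 of 135 therefore does not show how the preset correlation fares where genes vary together. Far fewer features changed in the simulations (200) than were called in the data (4204), so the shares called may differ there.

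The alternatives were a replicate block, quantile normalization, median centring, 2 filters on dim features, intensity trends, leaving out each array, averaging the features of a gene, 2 stricter thresholds and an ordinary equal-variance test. For lists, camera on ranks and the fry test were added to these. With 2 arrays per group, outlying samples and other splits of the samples were not tested.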

Results

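The 4 arrays comprised 2 of FTSC, which are human fallopian tube stem cells grown on feeder cells, and 2 of FTSC-ALI, in which such cells had been differentiated at an air-liquid interface. An air-liquid interface culture exposes the upper side of an epithelial layer to air and is commonly used to obtain ciliated and secretory cells. Each array gave a deposited log2 expression value for 22011 features. The arrays of a group resembled each other more than those of different groups. Pearson's r across features was 0.983 between the FTSC arrays and 0.985 between the FTSC-ALI arrays, against 0.934 to 0.944 between groups. The SD of the differences between arrays was 0.36 and 0.33 within groups and 0.65 to 0.69 between them. These are descriptions across features, which are not independent replicates.

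The comparison of FTSC-ALI with FTSC asked which genes differed between differentiated and undifferentiated cells. In FTSC-ALI, most measured genes of the ciliary axoneme, of glycolysis and the hypoxia response and of antigen presentation were called higher. Of 28 secretory cell markers, 13 were called higher and 3 lower. Most measured genes of DNA replication, mitosis and histone synthesis were called lower. Camera called each of these lists with its preset correlation and none with an estimated correlation (adjusted p of 0.167 to 0.322). With an estimated correlation, camera also called 0 of 25 lists shifted by 0.5 in simulation. Larger shifts were not simulated, so how much a missing call decides for lists with larger medians is not known. The largest called increase was that of HLA-DRA, the alpha chain of an MHC class II molecule, at 46.2-fold, and the largest called decrease that of the histone gene H2AC21, which was 11.5-fold higher in FTSC. By limma, 4204 features (19.1%) changed, of which 2189 were higher and 2015 lower in FTSC-ALI. Of these, 1857 changed at least 2-fold, 1087 of them upwards and 770 downwards. Among genes with a feature of their own, 1554 were higher and 1448 lower. Both arrays of a group lay above both of the other for 13954 features (63.4%, where chance gives 33.3%), and for all 4204 that changed.

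The number of changed features rested on all 4 arrays. It was 2027 without FTSC replicate 1, 2393 without FTSC replicate 2, 2051 without FTSC-ALI replicate 1 and 1957 without FTSC-ALI replicate 2. An ordinary equal-variance test, which borrows no spread from other features, called 7 features after adjustment and 5570 at an unadjusted p under 0.05.

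**Figure D1:**
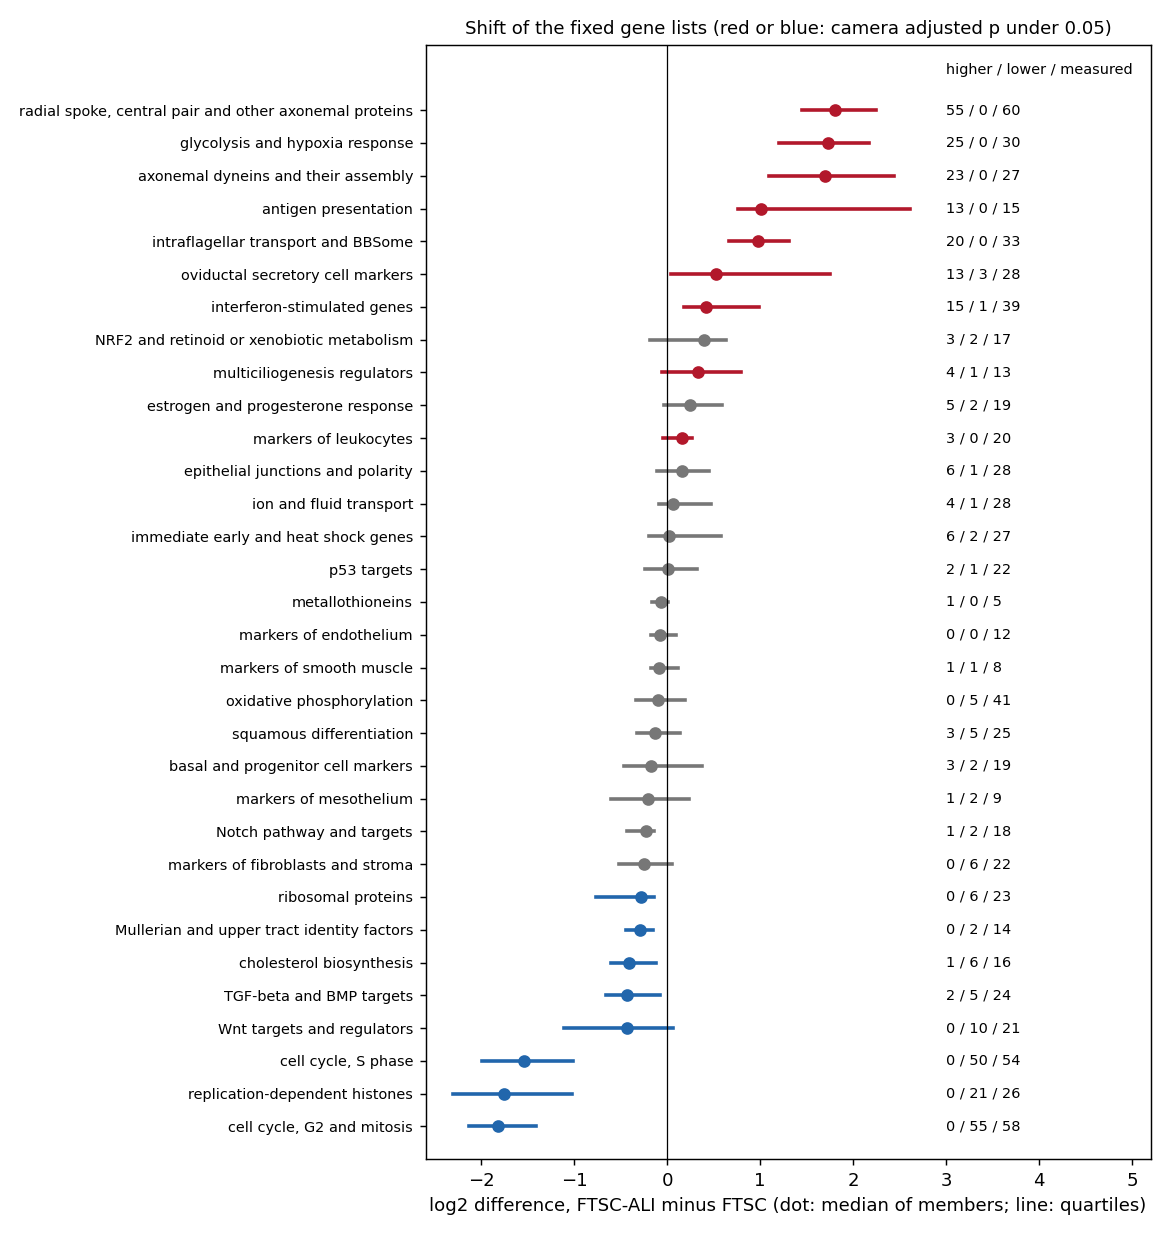
Median log2 difference, FTSC-ALI minus FTSC, of the measured members of each of the 32 gene lists (dots, with lines from the lower to the upper quartile), with the numbers of members called higher, called lower and measured at the right; red and blue mark lists called by camera with the preset correlation. The axonemal, glycolysis and antigen presentation lists lie at medians of 1.01 to 1.80, and the S phase, histone and mitosis lists at -1.54 to -1.82.

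Among the 12 largest increases, 2 were MHC class II genes. HLA-DRA (feature 2903189) rose from 3.77 ± 0.70 to 9.30 ± 0.01 (log2 values, mean ± SD, n = 2 arrays per group), a difference of 5.53 (SE 0.33, adjusted p = 0.00199). HLA-DPA1 (feature 2950329) rose 23.4-fold. PLAC8 (feature 2775909) rose from 3.45 ± 0.23 to 8.71 ± 0.05, or 38.4-fold (adjusted p = 0.00199), and PLAAT2, a phospholipase and acyltransferase, 31.5-fold. Genes known for roles in iron handling, the acute phase or innate defence were also in this set, though no list for these roles was fixed beforehand. CP, which encodes the copper-carrying ferroxidase ceruloplasmin, rose 21.3-fold and SLC40A1, the iron exporter ferroportin, 11.6-fold. CFB, complement factor B, rose 10.9-fold and LCN2, the iron-scavenging protein lipocalin 2, 10.7-fold. The others were SAA4, a serum amyloid A gene, at 19.8-fold, and EGLN3, a prolyl hydroxylase of the hypoxia response, whose log2 value rose by 3.71. LAPTM5, a lysosomal membrane protein known from blood cells, rose 10.3-fold and RGS22 10.2-fold.

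The 12 largest decreases were mainly of histone and cell cycle genes. H2AC21 (feature 2434129) fell from 9.76 ± 0.03 to 6.24 ± 0.07 (SE of the difference 0.13, adjusted p = 0.00199). The histone genes H2BC14 and H3C3 were 9.46-fold and 9.24-fold higher in FTSC. MKI67, the proliferation marker Ki-67, fell from 7.71 ± 0.09 to 4.57 ± 0.09, being 8.82-fold higher in FTSC (adjusted p = 0.00199). PBK, a mitotic kinase, was 9.85-fold higher in FTSC, CDKN3 8.40-fold, DTL 7.67-fold, CDC6, a replication licensing factor, 7.54-fold and GINS2, part of the replicative helicase, 7.47-fold. PSAT1, an enzyme of serine synthesis, was 11.3-fold higher in FTSC, FAM111B 9.40-fold and NRN1 7.29-fold. All 24 of these genes were called without each array in turn. Histone, HLA, SAA and IFIT genes belong to families whose members are alike to differing degrees. Signal shared between members was not tested, so values of single members may be uncertain.

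**Figure D2:**
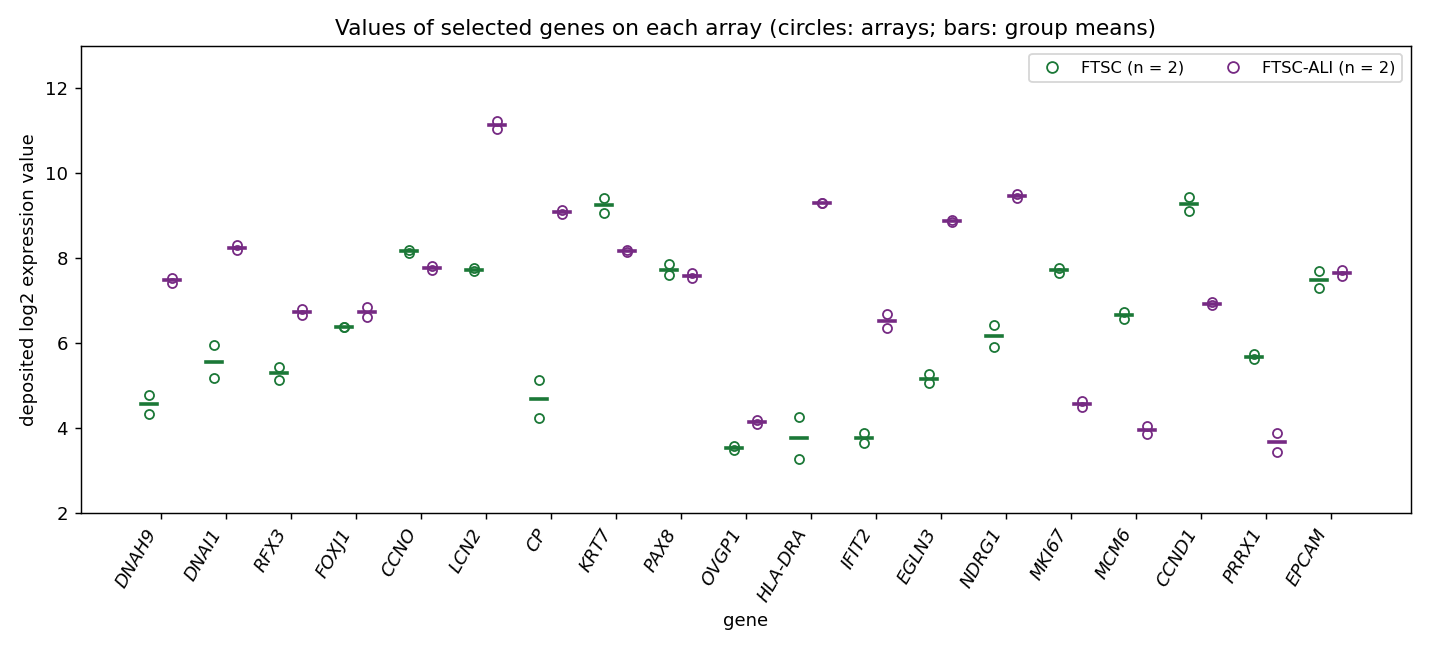
Deposited log2 expression values of 19 genes on each array (circles, 2 per group) with group means (bars), in FTSC (green) and FTSC-ALI (purple). HLA-DRA, CP and DNAH9 lie higher in both FTSC-ALI arrays, MKI67, MCM6 and CCND1 lower, and the FOXJ1 means of 6.38 and 6.73 differ by less than the test could call.

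Genes of the motile ciliary axoneme rose together. Of 27 measured genes of axonemal dyneins and their assembly, 23 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 difference of 1.70. DNAH9, an outer arm dynein heavy chain, rose from 4.56 ± 0.32 to 7.48 ± 0.09 (SE 0.19, adjusted p = 0.00214), or 7.56-fold. DNAH5, another outer arm heavy chain, rose 6.89-fold, DNAI1, an intermediate chain, 6.42-fold and the assembly factor DNAAF6 7.30-fold. Of 60 measured genes of radial spokes, the central pair and other axonemal parts, 55 rose and 0 fell (59 and 0 adjusted over the list alone), with a median of 1.80. STOML3 rose 7.48-fold, FAM216B 7.07-fold, CFAP52 6.12-fold and TTC29 6.11-fold. The log2 difference of FAM216B, 2.82 with all arrays, was 2.15 without FTSC replicate 1 and 3.50 without FTSC replicate 2. Camera gave an adjusted p of 1.15e-16 for the dynein list (adjusted p = 0.313 with an estimated correlation) and of 8.04e-29 for the other axonemal list (adjusted p = 0.322 with an estimated correlation).

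Intraflagellar transport and BBSome genes, whose products carry cargo along cilia, were higher for 20 of 33 measured members and lower for 0 (28 and 0 adjusted over the list alone). The median log2 difference was 0.98, and the camera adjusted p was 6.62e-13 (adjusted p = 0.345 with an estimated correlation). IFT172 rose from 5.08 ± 0.28 to 6.92 ± 0.07 (SE 0.18, adjusted p = 0.0044), BBS9 rose 3.64-fold, IFT46 3.27-fold and WDR19 3.19-fold. The 20 became 11 without FTSC replicate 1, 13 without FTSC-ALI replicate 1 and 13 without FTSC-ALI replicate 2.

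Of 13 measured regulators of multiciliogenesis, 4 rose and 1 fell (5 and 2 adjusted over the list alone), with a median log2 difference of 0.33. The kinase gene NEK10 rose by 2.43 (SE 0.23, adjusted p = 0.00429), and the transcription factor genes RFX3 and RFX2 by 1.43 and 1.07. CCDC78 rose by 0.80 and HYLS1 fell by 0.73, but neither was called when any 1 of the arrays was left out (adjusted p of 0.0584 to 0.0914 for CCDC78 and 0.0615 to 0.137 for HYLS1). FOXJ1, the master regulator of motile cilia, was 6.38 ± 0.01 in FTSC and 6.73 ± 0.16 in FTSC-ALI, a difference of 0.35 (95% interval -0.01 to 0.72, adjusted p = 0.154). CCNO, which promotes centriole amplification, gave -0.40 (95% interval -0.73 to -0.07, adjusted p = 0.0946). The list's camera adjusted p of 0.0464 became 0.147 without FTSC replicate 1 and 0.0883 without FTSC-ALI replicate 1 (adjusted p = 0.536 with an estimated correlation). It was 0.0518 after median centring, 0.0648 without the dimmest 25% of features, 0.0647 on ranks and 0.0704 with fry.

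Of 28 measured markers of oviductal secretory cells, 13 rose and 3 fell (17 and 4 adjusted over the list alone), with a median log2 difference of 0.52 and a camera adjusted p of 3.48e-05 (adjusted p = 0.205 with an estimated correlation). The largest increases were those of CP, LCN2, PIGR, the polymeric immunoglobulin receptor, at 8.40-fold, and complement C3 at 5.01-fold. CP, LCN2 and C3 are also known as acute phase genes. OVGP1, the oviductal glycoprotein, rose by 0.61 from 3.53 ± 0.06 (adjusted p = 0.0337), a call lost without any 1 of the arrays (adjusted p of 0.0768 to 0.165). PAX8, a transcription factor used to mark secretory cells, was 7.73 ± 0.18 in FTSC and 7.59 ± 0.08 in FTSC-ALI (difference -0.13, 95% interval -0.52 to 0.25, adjusted p = 0.577). KRT7, a simple epithelial keratin, fell by 1.08 (adjusted p = 0.0136, and 0.0518 without FTSC-ALI replicate 2). The 3 that fell became 1 without FTSC replicate 1, 1 without FTSC-ALI replicate 1 and 0 without FTSC-ALI replicate 2.

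Transcription factors and signals that pattern the Müllerian duct were called lower as a list by camera with its preset correlation, with 0 of 14 measured members higher and 2 lower (0 and 2 adjusted over the list alone). WNT7A fell by 1.73 (SE 0.24, adjusted p = 0.0106) and EMX2 by 0.87 (adjusted p = 0.0121). EMX2 was not called without FTSC-ALI replicate 1 or without FTSC-ALI replicate 2 (adjusted p up to 0.0611), and the count was then 1. The list's median was -0.29 and its camera adjusted p 0.0128 (adjusted p = 0.351 with an estimated correlation). It was 0.0543 without the dimmest 50% of features and 0.0615 with fry, so the list was not called there.

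Basal and progenitor markers went both ways. Of 19 measured, 3 rose and 2 fell (4 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.919). Its median was -0.17 and its mean 0.16, and the test's direction was downward. ALDH1A1, a retinaldehyde dehydrogenase used as a stem cell marker, rose by 2.54 (SE 0.25, adjusted p = 0.00475), PROM1, which encodes CD133, by 1.74 and the basal keratin gene KRT15 by 1.67. LGR6 fell by 0.98 (adjusted p = 0.0097). LGR5, a Wnt-associated stem cell receptor, gave 0.77 (95% interval -0.01 to 1.54, adjusted p = 0.148, and 0.042 without FTSC replicate 2). CD44 gave -0.50 (95% interval -0.83 to -0.18, adjusted p = 0.0503) and SOX9 -0.42 (95% interval -0.78 to -0.06, adjusted p = 0.102). CD44 passed at 0.0421 after quantile normalization. ITGA2, the other member that fell, did so by 0.69, and the number that fell was 1 without each array in turn.

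Cell cycle genes were lower in FTSC-ALI almost throughout. Of 54 measured S phase genes, 50 fell and 0 rose (52 and 0 adjusted over the list alone), with a median log2 difference of -1.54. MCM6, a subunit of the replicative helicase, fell from 6.65 ± 0.11 to 3.96 ± 0.14 (SE 0.15, adjusted p = 0.00199). Of 58 measured genes of G2 and mitosis, 55 fell and 0 rose (58 and 0 adjusted over the list alone), with a median of -1.82. BIRC5, or survivin, was 5.92-fold higher in FTSC and PLK1, a mitotic kinase, 5.83-fold. Of 26 measured replication-dependent histone genes, 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -1.75, and 13 fell without FTSC replicate 2. H1-1 fell by 2.80 and H3C12 by 2.52. Camera gave adjusted p of 4.05e-28 for S phase (adjusted p = 0.167 with an estimated correlation) and 5.34e-32 for G2 and mitosis (adjusted p = 0.167 with an estimated correlation). For the histones it gave 7.35e-14 (adjusted p = 0.206 with an estimated correlation).

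Wnt targets and regulators were lower, with 10 of 21 measured members down and 0 up (11 and 1 adjusted over the list alone). CCND1, or cyclin D1, fell by 2.36 (SE 0.16, adjusted p = 0.00229), and DKK1, a secreted Wnt inhibitor, was 3.68-fold and the transcription factor gene LEF1 2.43-fold higher in FTSC. Without FTSC replicate 2, 2 members were called higher. The median was -0.44 and the camera adjusted p 0.00272 (adjusted p = 0.246 with an estimated correlation). TGF-beta and BMP targets were lower for 5 and higher for 2 of 24 measured members (11 and 2 adjusted over the list alone), with a median of -0.44 and a camera adjusted p of 0.0128 (adjusted p = 0.290 with an estimated correlation), which was 0.178 without the dimmest 50% of features. THBS1, an activator of TGF-beta, fell by 1.30 and BAMBI, a decoy receptor, by 1.05, while CCN2 rose 2.01-fold. The 5 that fell became 3 without FTSC replicate 1, 2 without FTSC replicate 2, 3 without FTSC-ALI replicate 1 and 3 without FTSC-ALI replicate 2, and CCN2 was not called without FTSC replicate 1 or FTSC-ALI replicate 1. The Notch list was not called (1 higher and 2 lower of 18, or 1 and 0 adjusted over the list alone, camera adjusted p = 0.0566), although it was at 0.0421 without FTSC replicate 1. MAML3 rose by 0.81, and HES6 and NOTCH1 were the members called lower. The count that rose was 0 without each array in turn, and the count that fell was 0 without FTSC replicate 2 or FTSC-ALI replicate 2 and 1 without FTSC-ALI replicate 1. The TGF-beta and BMP targets that rose numbered 0 to 1 when 1 array was left out.

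Glycolysis and hypoxia response genes rose in FTSC-ALI. Of 30 measured, 25 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 difference of 1.73. NDRG1, a hypoxia-induced gene, rose from 6.18 ± 0.36 to 9.46 ± 0.07 (SE 0.20, adjusted p = 0.00199), or 9.73-fold. BNIP3, a mitochondrial autophagy receptor, rose 6.96-fold and the glycolytic aldolase gene ALDOC 6.82-fold. The camera adjusted p was 1.30e-19 (adjusted p = 0.167 with an estimated correlation). Oxidative phosphorylation genes were lower for 5 and higher for 0 of 41 measured members (4 and 0 adjusted over the list alone), and the list was not called (median -0.10, camera adjusted p = 0.218, and 0.0443 without FTSC replicate 1). The 5 became 0 without FTSC replicate 1 or FTSC-ALI replicate 1 and 1 without FTSC replicate 2 or FTSC-ALI replicate 2.

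Antigen presentation genes rose for 13 of 15 measured members and fell for 0 (13 and 0 adjusted over the list alone), with a median log2 difference of 1.01 and a camera adjusted p of 5.03e-08 (adjusted p = 0.167 with an estimated correlation). HLA-DPB1 rose from 3.33 ± 0.27 to 6.33 ± 0.06 and HLA-DMB, part of the peptide-loading chaperone for MHC class II, 6.45-fold. The 13 became 8 without FTSC replicate 2 and 7 without FTSC-ALI replicate 1. Interferon-stimulated genes rose for 15 and fell for 1 of 39 measured members (16 and 1 adjusted over the list alone), with a median of 0.41 and a camera adjusted p of 8.22e-07 (adjusted p = 0.167 with an estimated correlation). IFIT2 rose by 2.77 (SE 0.18, adjusted p = 0.00209), IFIT3 by 1.66 and the chemokine gene CXCL10 by 1.61. OAS3 fell by 0.68, a call lost without each array in turn. Among leukocyte markers, LAPTM5 rose by 3.37, CD68, a lysosomal protein of macrophages, by 1.69 and LYZ, or lysozyme, by 1.63, and the other 17 of 20 measured were not called (3 and 0 adjusted over the list alone, median 0.16). The leukocyte list's camera adjusted p of 0.0465 became 0.125 without FTSC replicate 2 and 0.0956 without FTSC-ALI replicate 1 (adjusted p = 0.380 with an estimated correlation). It was 0.0961 after quantile normalization, 0.279 without the dimmest 25% of features, 0.0595 on ranks, 0.0523 with a replicate block and 0.0520 and 0.0517 with intensity trends. LYZ, which was also on the list of secretory markers, was not called without FTSC replicate 1 or FTSC replicate 2.

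Of 67 listed ribosomal protein genes, only 23 were measured by a feature of their own, so the rest are not covered. Among the 23, 6 were lower and 0 higher (7 and 0 adjusted over the list alone). Their median was -0.28 and the camera adjusted p 0.00159 (adjusted p = 0.246 with an estimated correlation). RPL6 fell by 1.80 and RPL4 by 1.18. The 6 became 2 without FTSC replicate 2 and 3 without FTSC-ALI replicate 2. Cholesterol biosynthesis genes were lower for 6 and higher for 1 of 16 (6 and 1 adjusted over the list alone), with DHCR7, the last enzyme of the pathway, down by 0.96 and INSIG1, which restrains the pathway, up by 0.78. INSIG1 was not called without any 1 of the arrays (adjusted p of 0.0589 to 0.104), and DHCR7 was not called without FTSC replicate 1 or FTSC-ALI replicate 2 (adjusted p up to 0.057). The median was -0.42, and the camera adjusted p of 0.0279 became 0.106 without FTSC replicate 2 and 0.0757 without FTSC-ALI replicate 1 (adjusted p = 0.313 with an estimated correlation). It was 0.106 without the dimmest 50% of features and 0.0655 without the dimmest 25%. The number of cholesterol genes that rose was 0 without each array in turn. The 6 lower ones became 0 without FTSC replicate 1 or FTSC-ALI replicate 2 and 1 without FTSC replicate 2 or FTSC-ALI replicate 1.

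The remaining lists were not called. Estrogen and progesterone response genes were higher for 5 and lower for 2 of 19 (6 and 3 adjusted over the list alone, camera adjusted p = 0.0537), with STC2 up by 2.58 and the carbonic anhydrase gene CA12 by 1.71. Junction and polarity genes were higher for 6 and lower for 1 of 28 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0537), with the tight junction gene CLDN4 up by 1.69 and the epithelial factor ELF3 by 1.21. These lists passed at 0.0395 and 0.0405 after quantile normalization. EPCAM, an epithelial adhesion molecule, was 7.50 ± 0.29 in FTSC and 7.65 ± 0.10 in FTSC-ALI (difference 0.16, 95% interval -0.31 to 0.62, adjusted p = 0.592, and -0.05 without FTSC replicate 1). Ion and fluid transport genes were higher for 4 and lower for 1 of 28 (4 and 1 adjusted over the list alone, camera adjusted p = 0.110), with KCNE1 up by 1.63 and the sodium channel subunit SCNN1G by 1.10. The number of junction genes that rose was 2 to 4 when 1 array was left out, and that of estrogen and progesterone response genes 3 to 4. The numbers that fell were then 0 to 1 in both of these lists and 0 for ion and fluid transport.

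Squamous differentiation genes were lower for 5 and higher for 3 of 25 (6 and 3 adjusted over the list alone, camera adjusted p = 0.194), with the kallikrein genes KLK6, KLK10 and KLK7 down by 1.99, 1.75 and 1.62. Immediate early and heat shock genes were higher for 6 and lower for 2 of 27 (6 and 3 adjusted over the list alone, camera adjusted p = 0.224), with ZFP36 up by 1.67 and ATF3 by 1.54. NRF2, retinoid and xenobiotic genes were higher for 3 and lower for 2 of 17 (5 and 2 adjusted over the list alone, camera adjusted p = 0.189). DHRS3, a retinal reductase, rose by 3.21 and CYP1B1 by 2.49, and the cystine transporter gene SLC7A11 fell by 1.60. Of 22 measured p53 targets, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.719), with SPATA18 up by 1.99, TP53INP1 up by 1.74 and the pro-apoptotic gene BAX down by 1.31. MT3 rose by 1.58 and was the only called gene of 5 measured metallothioneins (1 and 0 adjusted over the list alone, camera adjusted p = 0.816, with a median of -0.07, a mean of 0.19 and an upward test). When 1 array was left out, the squamous genes that rose numbered 0 to 1, the immediate early genes that fell 0 to 2, the NRF2 list's members that fell 1 and the p53 targets that fell 1 to 2.

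Markers of other cell types were measured in the same arrays. Fibroblast and stromal markers were lower for 6 and higher for 0 of 22 (7 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 0.0537, and 0.0314 after quantile normalization). PRRX1, a mesenchymal transcription factor, fell by 2.02 (SE 0.19, adjusted p = 0.00417) and COL1A1, a chain of type I collagen, by 0.85, while VIM gave 0.26 (95% interval -0.21 to 0.72, adjusted p = 0.376). The 6 became 1 without FTSC replicate 1, 3 without FTSC replicate 2, 1 without FTSC-ALI replicate 1 and 2 without FTSC-ALI replicate 2, and COL1A1 was called only without FTSC replicate 2 (adjusted p of 0.0486 to 0.0806). Per the labels, FTSC were grown on 3T3 feeder cells, a fibroblast line. Whether feeder RNA reached the FTSC arrays was not tested, so none of these differences is assigned to it. Smooth muscle markers were higher for 1, MYLK, and lower for 1, CALD1, of 8 (1 and 1 adjusted over the list alone, camera adjusted p = 0.881), with a downward test that turned upward after quantile normalization. MYLK and CALD1 were each not called in 3 of the 4 omissions of an array (adjusted p up to 0.0641 and 0.0705). Of 12 endothelial markers, 0 were called by limma (0 and 0 adjusted over the list alone, camera adjusted p = 0.881), with EMCN at 0.36 (adjusted p = 0.148) having the smallest p. Mesothelial markers were higher for 1 and lower for 2 of 9 (2 and 2 adjusted over the list alone, camera adjusted p = 0.719), with CALB2 at 0.60 (adjusted p = 0.0498) not called without any 1 of the arrays (adjusted p of 0.0866 to 0.218) and the number that fell then at 0 to 2. ACTB, the cytoskeletal actin gene, gave -0.38 (95% interval -0.80 to 0.04, adjusted p = 0.172).

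The FTSC arrays differed from each other in the axonemal genes, and in some other genes that rose in FTSC-ALI. Of the 87 measured members of the axonemal lists, 79 were higher in FTSC replicate 2 than in FTSC replicate 1, with a median log2 difference of 0.55, while the FTSC-ALI arrays differed by a median of -0.01. The median difference between the FTSC arrays was 0.37 for intraflagellar transport genes, -0.03 for S phase genes, 0.16 for genes of G2 and mitosis, 0.14 for histone genes, -0.07 for the called glycolysis and hypoxia genes, -0.05 for antigen presentation genes and 0.03 for secretory markers. Single genes of these and other lists, chosen after their values were seen, were also higher in FTSC replicate 2. HLA-DRA was 3.28 in replicate 1 and 4.27 in replicate 2, HLA-DMB 4.55 and 5.67, CP 4.23 and 5.12, ALDH1A1 3.71 and 4.41 and DHRS3 4.85 and 5.51, while HLA-DPB1 was 3.52 and 3.13 and HLA-DOA 4.82 and 4.23. Without FTSC replicate 2, 24 dynein and 56 other axonemal genes rose, and without FTSC replicate 1, 20 and 51. Without FTSC-ALI replicate 1, 18 and 46 rose, and without FTSC-ALI replicate 2, 18 and 45.

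**Figure D3:**
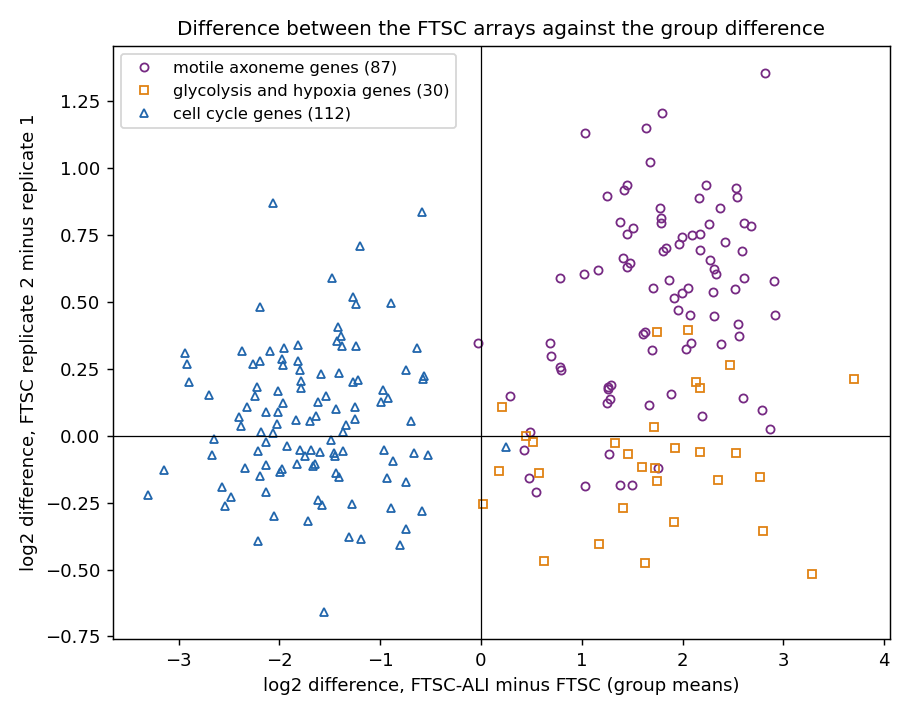
Log2 difference between the FTSC arrays (replicate 2 minus replicate 1, vertical) against the log2 difference between groups (FTSC-ALI minus FTSC, horizontal), 1 symbol per gene of the axonemal, glycolysis and cell cycle lists. Of the 87 axonemal genes, 79 lie above 0 on the vertical axis, at a median of 0.55, and the called glycolysis genes lie at a median of -0.07.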

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

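The setting that fitted only features with at least 1 gene symbol was chosen after seeing the data; the others were set before the data were examined. Of 150 named genes, 1 changed direction in any of up to 17 settings: EPCAM gave -0.048 without FTSC replicate 1, against 0.16 with all arrays (0.08 to 0.36 in the other omissions). Most settings changed the test, the threshold or the set of features and left a gene's difference as it was. Every called feature had both arrays of a group above both of the other, so omitting 1 array could not turn it. The count of turned genes is therefore little evidence of stability. Of the 139 named genes called, 90 were called without each array in turn and 49 lost the call without at least 1. With 1 array left out, the lone sample was assumed to vary like the other group. The number of changed features was then 1957 to 2393, with 1105 to 1400 higher and 837 to 993 lower, against 4204, 2189 and 2015; fewer samples were tested. Requiring a 2-fold change as well gave 1857 (1087 higher, 770 lower), and an adjusted p under 0.01 gave 1231 (735 and 496), of which all were among the 4204. The ordinary equal-variance test gave 7 (4 and 3), 5 of them among the 4204. Quantile normalization gave 4186 and median centring 4163, of which 58.0% were higher against 52.1%. The balance turned in fits on fewer features. Without the dimmest 50% of features 4374 changed, 46.5% of them higher, and without the dimmest 25% 4991 changed (49.1%). With 1-symbol features 4330 changed (48.6% higher), and with features of at least 1 symbol 4813 (48.9%). With the replicate number as a block, 3187 features changed, 3037 of them among the 4204. The labels do not say whether equal numbers share a donor, culture or day. The deviations of equal numbers correlated at 0.0404 across features, which shows no sign of pairing but does not exclude it. Dim features had no detection call, so depth of signal over background was not judged. Mean Pearson's r between groups was 0.939, and 0.876 with the dimmest 50% and 0.902 with the dimmest 25% of features left out.

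The lists of axonemal dyneins, other axonemal proteins, intraflagellar transport, secretory markers, S phase, G2 and mitosis, histones, Wnt, interferon, antigen presentation, glycolysis and ribosomal proteins kept direction and call in all 16 settings other than the estimated correlation. Values that follow are limma camera or fry adjusted p, and except where the setting itself shows it (fewer features or arrays), the cause was not tested. With the replicate block, Notch passed (0.0413) and leukocytes did not (0.0523). After quantile normalization, estrogen response (0.0395), junctions (0.0405) and fibroblasts (0.0314) passed, leukocytes did not (0.0961) and smooth muscle turned upward (0.993). After median centring, multiciliogenesis was not called (0.0518). Without the dimmest 50% of features, squamous (0.0304), estrogen response (0.0143) and ion transport (0.0297) passed, Müllerian factors (0.0543), TGF-beta targets (0.178) and cholesterol (0.106) did not, and basal markers turned upward (0.478). Without the dimmest 25%, junctions passed (0.0275), multiciliogenesis (0.0648), cholesterol (0.0655) and leukocytes (0.279) did not, and smooth muscle turned upward (0.888). With an intensity trend, junctions passed (0.0449) and leukocytes did not (0.0520), and with a robust trend likewise (0.0468 and 0.0517). With 1-symbol features, estrogen response (0.0461) and junctions (0.0476) passed and basal markers turned upward (0.955), and with features of at least 1 symbol likewise (0.0470, 0.0482 and 0.948). On ranks, Notch passed (0.0426), and multiciliogenesis (0.0647) and leukocytes (0.0595) did not. With fry, Notch (0.0351), estrogen response (0.00233), junctions (0.0149), ion transport (0.0337), p53 targets (0.0299) and NRF2 genes (0.0099) passed, multiciliogenesis (0.0704) and Müllerian factors (0.0615) did not, and basal markers turned upward (0.215). With an estimated correlation, none of the 17 called lists passed. It gave 0.167 for S phase, G2 and mitosis, interferon, antigen presentation and glycolysis, 0.205 for secretory markers, 0.206 for histones and 0.246 for Wnt and ribosomal proteins. It gave 0.290 for TGF-beta targets, 0.313 for dyneins and cholesterol, 0.322 for other axonemal proteins, 0.345 for intraflagellar transport, 0.351 for Müllerian factors, 0.380 for leukocytes and 0.536 for multiciliogenesis. With 1 array left out, the range was 0.0126 to 0.147 for multiciliogenesis, 0.0421 to 0.126 for Notch, 0.0443 to 0.801 for oxidative phosphorylation, 0.00593 to 0.106 for cholesterol and 0.0294 to 0.125 for leukocytes. It was 0.504 to 0.9996 for endothelium, 0.802 to 0.994 for basal markers and 0.424 to 0.994 for metallothioneins, whose directions turned in at least 1 omission.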

Other observations

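The gene lists and tests in this part were all chosen after the values had been seen, so their p-values are no independent support. The added lists hold genes already reported above as rising. Among these were SAA4 in the NF-kB and acute phase list and CFB and C3 in the complement list. Of 27 measured genes listed as targets of NF-kB or acute phase genes, many of which respond to inflammatory signals, 15 were higher and 1 lower in FTSC-ALI. The median log2 difference was 0.74, and the limma camera adjusted p over the 3 added lists was 6.18e-07 (adjusted p = 0.0743 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 2.95 (SE 0.14, adjusted p = 0.00199), CCL20 by 2.21 and TNFAIP3, a feedback inhibitor of NF-kB, by 1.98. IL1B rose by 1.83, NFKBIA by 1.55 and CXCL8 by 1.54, while IL18 fell by 1.40. NFKB2 and RELB gave 0.02 and 0.01. CRP gave -0.01 (limma adjusted p = 0.968) and IL6 -0.40 (limma adjusted p = 0.0986), so neither was called. Complement genes were higher for 7 and lower for 0 of 22 (median 0.14, adjusted p = 0.00205, adjusted p = 0.0771 with an estimated correlation), with C6 up by 2.98, the C1 inhibitor SERPING1 by 2.84 and CFI by 2.52.

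Genes of ribosome biogenesis and the nucleolus fell for 24 of 35 measured and rose for 0. The median was -0.92 and the limma camera adjusted p 1.92e-13 (adjusted p = 0.0743 with an estimated correlation). DDX21, a nucleolar helicase, fell from 7.11 ± 0.18 to 5.26 ± 0.13 (SE 0.16, adjusted p = 0.00347, n = 2 arrays per group). MRTO4, EXOSC2 and NOP16 had log2 differences of -1.83, -1.76 and -1.59, and FBL, or fibrillarin, of -0.92. The 23 measured of 67 listed ribosomal protein genes had a smaller median of -0.28, and the difference between these lists was not tested.

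Axonemal genes were higher in FTSC replicate 2 than in replicate 1, by a median of 0.552 on the log2 scale. Array noise or normalization was not excluded. Random lists of unrelated genes had medians of -0.0625 to 0.0777 in their central 95%, but comparing the axonemal lists with them only restates the pattern. The estimated correlations of the axonemal lists, 0.460 and 0.631, come from residuals of the same arrays, which hold this difference. They therefore decide nothing on its source. A uniform carry-over of differentiated cells or RNA would raise other FTSC-ALI genes alike. Shares were compared on the unlogged scale, on which mixed RNA adds up. The called glycolysis genes gained a median of -2.75% of the distance from replicate 1 to the FTSC-ALI mean, against 11.9% for the called axonemal genes. The difference was -14.65 percentage points (95% bootstrap interval -17.3 to -11.4, with genes taken as independent). That interval covers the spread over genes on 1 pair of arrays, not the spread between arrays or cultures. The axonemal lists were examined because they differed between these arrays, so their larger share partly restates that choice. The unequal shares show only that these lists did not gain 1 common share. Carry-over beside another change or array noise could also give that. On the unlogged scale, called antigen presentation genes gained a median of -3.02%, secretory markers called higher 2.53% and intraflagellar transport genes called higher 12.6%. Lists with few genes called higher ranged from -12.8% for immediate early and heat shock genes to 21.5% for TGF-beta and BMP targets. Single genes gained more, among them HLA-DMB (13.8%) and ALDH1A1 (9.73%), with HLA-DRA at 1.54%. Carry-over of some differentiated cells, such as ciliated cells, remains possible, or a few cells in replicate 2 may have begun to differentiate, and no biological explanation was tested because the design names none within FTSC.

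MHC class II genes and LAPTM5 rose in FTSC-ALI, HLA-DRA by 5.53, and 2 further leukocyte markers, CD68 and LYZ, rose by 1.69 and 1.63. LYZ was also on the list of secretory markers, so its rise does not point to leukocytes alone. Leukocytes among the FTSC-ALI cells were not excluded. PTPRC, CD53, TYROBP and AIF1 had log2 differences of 0.18, 0.36, -0.27 and 0.10, with 0.729 as the highest upper 95% limit, but whether these features were above background was not measured, so the bound set for them decides nothing. The RNA kit cannot be told apart from the group, since 0 kits were used in both. Differentiation, the difference the design names, also stays open as untested.

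Axonemal genes rose while FOXJ1 and CCNO did not pass the test. Compression of differences at the level of FOXJ1 and above, and regulators already transcribed in FTSC, were both left undecided, because each test sets levels of different features against each other and these depend on their probes. The 14 axonemal genes at or above FOXJ1's FTSC mean had a median log2 difference of 1.648. FOXJ1, CCNO and CDC20B lay at or above the 81.38 percentile of all features in both FTSC arrays, while the other regulators that did not pass lay lower by their FTSC means, from 16.7 for DEUP1 to 74.2 for MYB. Kit and group cannot be told apart here either.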
